A study of Gallus gallus with 20 samples.

How the data were processed

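The data are RNA-seq of chicken (Gallus gallus) micromass cultures, 20 libraries in 10 groups of 2: cells carrying 1 of 9 HOX transgenes, and Ctrl. Groups and replicate numbers were taken from the sample titles and infection labels. Per the labels' protocols, mesenchymal cells of limb buds were infected with an RCASBP virus carrying the transgene and cultured for 6 days, RNA was taken before the cells were fixed for a binding assay, polyadenylated RNA was selected, and libraries were sequenced as single reads. The labels differ on the stage of the limb buds: the growth protocol gives Hamburger-Hamilton stage 24 and the cell type label stage 25. The label of Ctrl gives its infection as none, while a general protocol text says that cells were infected.

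The authors deposited a table of read counts per gene for all libraries. The values were whole numbers with different totals per library, and the column names end as STAR's sorted alignments do. STAR, DESeq2 and the genome build galGal4 are named in the submitters' processing notes, with no version. The counting tool, its annotation and whether it used strand are not given in the sources used here. Genes that overlap or run antisense to each other, and genes with close copies such as class I MHC and globin genes, are therefore uncertain. The table has 32787 rows, 14099 with a gene symbol, 3215 with an Ensembl identifier alone and 15473 with an assembled locus name, and 4399 were at 0 in all libraries. COL2A1, the main collagen of cartilage, is listed at 0 in all 20 libraries, so its level is not read here. Symbols are those of the table. In 12 rows both libraries of a group hold the fixed value 1000, most often in the row of the group's own HOX gene. Those rows were left out of the library totals and of the tests, and the endogenous level of such a HOX gene was fitted over the other groups alone. Total counts ran from 16354251 to 38210189 with a median of 26035902, and the self-test below gives the precision that this depth and 2 libraries per group allow. The counts of 7 tested rows equal those of another row in all libraries.

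Low counts were filtered with edgeR's filterByExpr by group, which left 18299 genes, 11344 of them with a symbol. Libraries were scaled by TMM. A group means model was fitted to all 20 libraries with edgeR's quasi-likelihood method (edgeR 4.0.16, limma 3.58.1, R 4.3.3), so that every comparison shares 1 estimate of the spread per gene, with 10 residual degrees of freedom, 3.75 prior degrees of freedom and a common dispersion of 0.0399. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were each HOX group against Ctrl, each against the unweighted mean of the other HOX groups, all HOX groups against Ctrl, any difference among the HOX groups (an F test), same-number HOXA against HOXD, HOXA13 and HOXD13 against the groups of numbers 9 to 11, and a split of the factors by binding, taken from knowledge of the study and not from these libraries, whose membership was not checked. Fitted to a group with 1 library, as happens when a replicate is left out, the model assumes that this library varies like those of the other groups. CPM in the text are counts scaled to TMM-adjusted library totals, and group distances used log2 CPM with a prior count of 2, without HOX genes. Distances were tested by exact one-sided permutation of the group pairs or splits.

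Of 25 gene lists, 24 were tested with camera on voom values, with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over all lists and comparisons of a family (240 tests against Ctrl, 216 against the other HOX groups, 96 of HOXA against HOXD and 48 between sets). The lists were cartilage matrix and its regulators, hypertrophy and bone, skeletal muscle, tendon and fibrous connective tissue, smooth muscle and contractile genes, limb patterning factors, BMP and GDF signalling, WNT signalling, FGF signalling, the retinoic acid pathway, Eph receptors and ephrins, cell adhesion and axon guidance, TALE cofactors with CTCF and cohesin, interferon and antiviral response, proliferation, unfolded protein and amino acid stress, immediate early and heat shock genes, hypoxia and glycolysis, cholesterol and lipid synthesis, and markers of endothelium, of blood and macrophages, of ectoderm and epithelium, of neural crest, glia and pigment, and of fat. HOX genes were described and not tested as a list. Names that point to the same row were counted once: 34 names gave 33 rows for interferon and antiviral genes, and 28 gave 27 for blood and macrophages. The rule for named genes took HOX genes first, then per comparison up to 8 higher and 8 lower genes with the largest absolute log2 fold change among called genes with a symbol, a mean of at least 5 CPM on the higher side and both libraries of each single group on the same side of the other side's mean, and for each list up to 6 called members by absolute log2 fold change and the members in places 1 to 4. This gave more genes than could be printed. Some of them are not reported here. Among them, genes whose call held with each library left out in turn were preferred, a choice made after their values were seen. The genes with opposite directions in same-number groups that the closing part names were chosen after their values were seen.

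The alternatives planned were DESeq2 1.42.0, RLE scaling, no filter on low counts, HOX genes left out, the replicate number as a block, a fit to only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were a term for the library number series (HOXA9, alone in its series, cannot be corrected), series 30 alone, HOXA9 left out, and both series 38 libraries left out. Genes called in all 9 comparisons with Ctrl, and genes called in both groups of the same number, were set against 20 simulations of unchanged groups. Whether a list was higher in replicate 1 or 2 was tested over the 10 groups with an exact sign test, and the correlation of same-numbered libraries by exchanging the numbers within groups in all 512 ways, both chosen after seeing the data. The steps were tested on simulated data made from the means and library sizes of HOXD9 and Ctrl over 17734 genes: of 100 genes changed 2-fold, 40 were recovered, and of 100 changed 4-fold, 77, with 1 unchanged gene called and a median error of 0.17 on the log2 scale. In the same comparison a list shifted by 0.5 log2 units had adjusted p = 1.43e-29 and 0 unshifted lists were called. In simulated groups with a planted pairing the distance test ranked it 1 of 24, and 15 of 24 with none planted. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.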

Results

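Chicken limb-bud mesenchymal cells were kept for 6 days as micromass cultures, dense drops in which such cells form cartilage. They carried an RCASBP retrovirus expressing 1 of 9 FLAG-tagged HOX genes (HOXA9, HOXA10, HOXA11, HOXA13, HOXD9, HOXD10, HOXD11, HOXD12 or HOXD13), and cells labelled as having no infection served as control (Ctrl). Polyadenylated RNA was sequenced from 2 libraries per group, 20 libraries in 10 groups. Total counts ran from 16354251 in HOXA9 replicate 2 to 38210189 in HOXD11 replicate 2, with a median of 26035902, and 18299 genes were tested, 11344 of them with a symbol. In what follows, a value in parentheses after a gene is its log2 fold change ± SE from edgeR's quasi-likelihood test. An adjusted p is that test's Benjamini-Hochberg value over all tested genes, and levels are mean counts scaled to library totals (CPM) ± SD with n = 2 libraries per single group. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Because Ctrl was not infected, each comparison with it holds the virus together with the HOX gene. The label check by transgene could not be made: the row of the group's own HOX gene held the fixed value 1000 in both libraries of each group except HOXA10, where it stood in 2 rows with an Ensembl identifier alone.

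The libraries differed in ways that the groups do not explain. Library numbers in the column names fell into 4 series: series 28 with 4 libraries (replicate 1 of HOXA10, HOXA13, HOXD10 and HOXD12), series 38 with 2 (replicate 2 of HOXD12 and of Ctrl), series 122 with both HOXA9 libraries, and series 30 with the other 12. The nearest library by expression belonged to the same series for 16 of 20 libraries and was the group's own replicate for 10. In Ctrl replicate 2 and HOXD12 replicate 2, 14.1% and 7.58% of the counts lay on 5 abundant loci without a name, against 0.294% to 1.05% in the other libraries. Rows named as ribosomal RNA held 0.312% and 0.217% of the counts in those libraries and at most 0.0170% elsewhere. Aggrecan (ACAN), the main proteoglycan of cartilage, ranged from 3838 CPM in Ctrl replicate 1 to 619 in Ctrl replicate 2, and from 3196 to 1048 in the HOXD12 replicates. Cartilage matrix genes as a list were higher in replicate 1 than in replicate 2 in 10 of 10 groups, by a median of 0.341 to 1.77 on the log2 scale (exact two-sided sign test p = 0.00195, the smallest it can give). Since series 122 holds HOXA9 alone, that series and the HOXA9 group cannot be told apart.

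The first question was how the mean of the 9 HOX groups differed from Ctrl (n = 18 against n = 2). Immediate early genes are transcription factors and feedback regulators that cells switch on within minutes of a stimulus. Of these, FOS rose (5.67 ± 0.30, adjusted p = 3.52e-07) from 23.9 ± 4.74 CPM in Ctrl to 1308 ± 483 CPM. EGR1 (3.37 ± 0.31), JUN (2.57 ± 0.21), BTG2 (2.76 ± 0.36) and the phosphatase gene DUSP1 (2.12 ± 0.32) rose as well. The cell adhesion gene CDH20 (3.89 ± 0.32, 14.1 ± 10.5 against 0.806 ± 0.191 CPM), the muscle growth inhibitor myostatin (MSTN, 3.84 ± 0.40) and the signalling gene WNT16 (3.34 ± 0.52, 9.76 ± 4.89 against 0.840 ± 0.347 CPM) were among the largest rises. MSTN in HOXD11 replicate 1 stayed at the Ctrl level (1.34 CPM). The gelatinase gene MMP9 (-2.38 ± 0.24, 3.02 ± 1.20 against 14.8 ± 0.836 CPM) fell while the collagenase gene MMP13 (2.02 ± 0.27) rose. The class I MHC genes BF1 (2.81 ± 0.25) and BFIV21 (1.58 ± 0.24) rose, whereas the antiviral gene OAS*A fell (-2.15 ± 0.21, 2.66 ± 1.41 against 10.3 ± 4.21 CPM). In all, 2308 genes passed the test, 981 higher and 1327 lower. Without Ctrl replicate 1 the count was 1382, and with series 30 alone, which leaves 1 Ctrl library, it was 4219.

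Grouped by the lists fixed before the data were examined, 7 of 21 immediate early and heat shock genes rose, 0 fell and 14 did not pass, against 9 higher and 0 lower adjusted over the list alone (camera: higher, adjusted p = 1.18e-08, or 0.378 estimated). Skeletal muscle genes gave 0 rises and 8 falls among 35, with 0 and 10 adjusted over the list alone (lower, adjusted p = 1.28e-06, or 0.696 estimated). In these list tests, the adjusted p with a preset correlation is followed by that with an estimated correlation (estimated) and by each one at which leaving out libraries or a series term ended the call. The giant sarcomere protein gene NEB (-2.32 ± 0.39) and the myosin gene MYH15 (-1.66 ± 0.22) were among those that fell. Among limb patterning factors, 11 of 47 rose, 4 fell and 32 did not pass, against 15 higher and 4 lower adjusted over the list alone (higher, adjusted p = 0.0186, or 0.402 estimated, and 0.16 without Ctrl replicate 1). IRX6 (1.18 ± 0.20) was among the rises. Among genes of tendon and fibrous connective tissue, 4 of 24 rose, 0 fell and 20 did not pass, against 5 higher and 0 lower adjusted over the list alone (higher, adjusted p = 0.0273, or 0.678 estimated, and 0.646 without Ctrl replicate 1). The collagen gene COL1A2 (0.76 ± 0.13) was 1 of them. WNT signalling genes gave 6 rises and 0 falls among 28, with 6 and 0 adjusted over the list alone (higher, adjusted p = 0.0164, or 0.217 estimated, and 0.0606 with the series term, 0.0739 within series 30 and 0.0516 without series 38). They included the secreted WNT inhibitor WIF1 (1.79 ± 0.29, 20.9 ± 16.1 against 4.69 ± 1.59 CPM) and the receptor FZD10 (2.01 ± 0.35). In HOXD9, WIF1 was not higher (3.31 and 4.48 CPM). The receptor EPHA4 (1.08 ± 0.09) rose with 4 of 14 Eph and ephrin genes, none of which fell, and 4 rose adjusted over the list alone (higher, adjusted p = 0.0202, or 0.277 estimated, and 0.293 without Ctrl replicate 1).

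Cholesterol and lipid synthesis genes were lower as a list against Ctrl, with 0 rising and 4 falling among 23, the same counts as adjusted over the list alone (adjusted p = 0.000958, or 0.749 estimated, and 0.113 without Ctrl replicate 1). For hypertrophy and bone, 3 of 21 rose, 1 fell and 17 did not pass, against 6 higher and 1 lower adjusted over the list alone (higher, adjusted p = 0.0249, or 0.805 estimated, and 0.38 without Ctrl replicate 2, 0.347 with the series term, 0.567 within series 30 and 0.289 without series 38). Interferon and antiviral genes gave 5 rises and 5 falls among 33, with 8 and 8 adjusted over the list alone. That list was not called (camera adjusted p = 0.746), and its test pointed up while its median (-0.03) and mean (-0.16) log2 fold changes were below 0. Of markers of ectoderm and epithelium, 2 of 22 rose, 0 fell and 20 did not pass, against 0 higher and 0 lower adjusted over the list alone (higher, adjusted p = 0.0336, or 0.833 estimated, and 0.312 without Ctrl replicate 2, 0.0912 with the series term, 0.327 within series 30 and 0.331 without series 38). Markers of blood and macrophages gave 1 rise and 2 falls among 27, with 1 and 2 adjusted over the list alone, and that list was not called (camera adjusted p = 0.87). The embryonic globin gene HBE (2.25 ± 0.42) rose, and the fatty acid binding protein gene FABP7 (-0.94 ± 0.13) and G0S2 (-1.59 ± 0.21) fell. HOXA13 had HBE at 5.31 and 1.99 CPM, Ctrl at 5.68 and 3.47. Over all list tests, 190 of 600 were called with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.115; the self-contained test fry called 86. The lists of TALE cofactors, CTCF and cohesin (lowest adjusted p = 0.196) and of the retinoic acid pathway (0.173) were called in none of the comparisons.

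**Figure D1:**
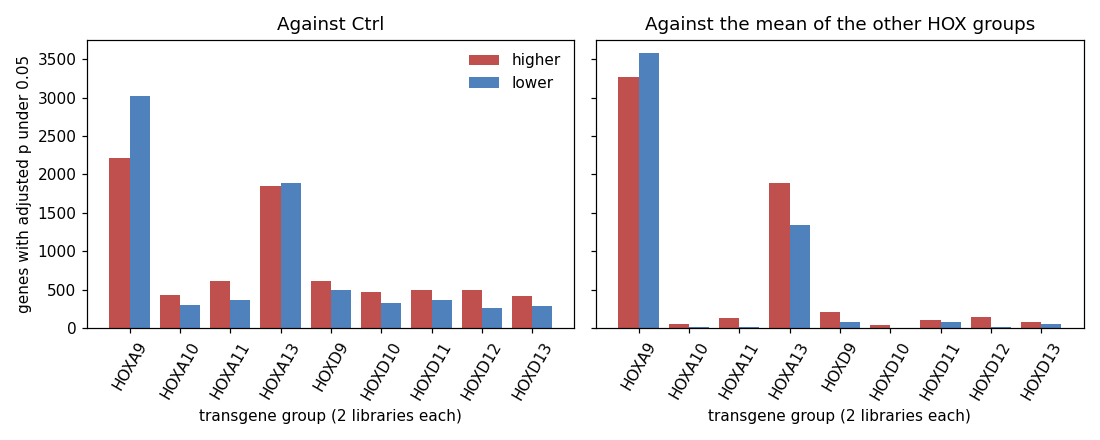
Number of genes with adjusted p under 0.05 (vertical axis) for each of the 9 HOX groups (2 libraries each), higher in red and lower in blue, against Ctrl on the left and against the mean of the other HOX groups on the right. HOXA9 (5231 and 6846 genes) and HOXA13 (3744 and 3240) stood above the other groups, of which the highest had 1112 against Ctrl and 295 against the other HOX groups.

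Against Ctrl, the 9 HOX groups taken singly shared 63 genes called higher and 66 called lower in every group. Lists drawn independently at the same sizes would share 2.7e-09 and 2.5e-10. In 20 simulations of unchanged groups against the same controls the highest count was 0 in both directions. That 0 was fixed beforehand, since each simulation had a mean of 0 to 0.111 called genes per comparison. At an unadjusted p under 0.05 the simulated mean was 7.35 higher and 1.4 lower, against 245 and 277 observed. The simulated groups held no change at all, so they do not account for an infection shared by the HOX groups. The controls number only 2 and were not split, so part of the excess may come from the shared controls. Leaving out a single library moved the total of 129 to between 59 and 151. It fell to 63 without HOXA10 replicate 1, 77 without HOXA10 replicate 2, 72 without HOXA11 replicate 1, 66 without HOXA11 replicate 2, 64 without HOXD9 replicate 1 and 59 without HOXD9 replicate 2. It was 67 without HOXD10 replicate 1, 62 without HOXD10 replicate 2, 81 without HOXD11 replicate 1, 65 without HOXD11 replicate 2, 81 without HOXD12 replicate 2, 62 without HOXD13 replicate 1 and 61 without HOXD13 replicate 2. With both series 38 libraries left out the total was 84, and 202 genes were shared with series as a term in the fit. FOS, EGR1 and BF1 were higher in every HOX library than in either Ctrl library. Fitted with only the 4 libraries of a group and Ctrl, so that no other library informs the spread, 1869 genes passed for HOXA9, 26 for HOXA13, 24 for HOXA11, 8 for HOXD9, 3 for HOXD12, 2 for HOXD10, 1 for HOXA10 and 0 for HOXD11 and HOXD13 in edgeR. For these, 2133 and 2502 genes had an unadjusted p under 0.05, and DESeq2 over all libraries called 1442 and 1268.

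**Figure D2:**
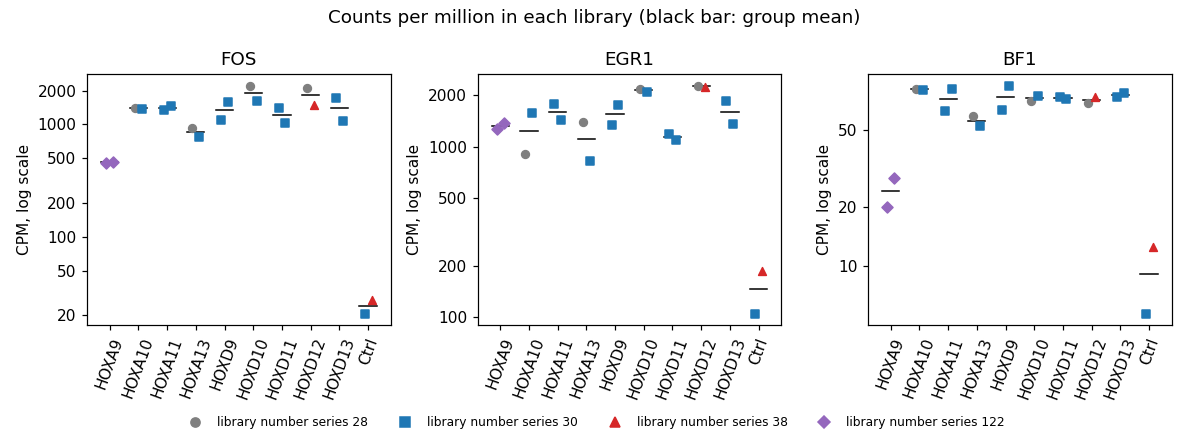
CPM of FOS, EGR1 and BF1 on a log axis in each library (points, shaped and coloured by library number series) with the group mean as a black bar. FOS lay at 20.6 and 27.3 CPM in the Ctrl libraries and at 454 CPM or above in every HOX library.

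Endogenous HOX genes could be read where their row held no fixed value. Over the HOX groups other than HOXD13, HOXD13 (1.22 ± 0.24, adjusted p = 0.00709) was higher than in Ctrl, and over those other than HOXA11, HOXA11 (-0.84 ± 0.17, adjusted p = 0.00792) was lower. With 1 control left out, both kept their direction at a larger SE: HOXD13 was at 0.91 ± 0.30 (adjusted p = 0.0994) without Ctrl replicate 1, and HOXA11 at -0.71 ± 0.23 (adjusted p = 0.0867) without Ctrl replicate 2. Over all alternatives their adjusted p ran from 1.26e-05 to 0.0994 and from 3.85e-05 to 0.0995. HOXA13 cultures had lower HOXA11 (-1.97 ± 0.25) and higher HOXD13 (1.78 ± 0.30) than Ctrl, and HOXA9 cultures had lower HOXA11 (-1.69 ± 0.25), HOXD3 (-1.34 ± 0.15) and HOXD8 (-1.10 ± 0.15).

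Cultures with HOXA9, a factor of the proximal limb, had the most called genes. Against Ctrl, the adhesion receptor gene ADGRG7 (5.85 ± 0.49, 19.5 ± 5.05 against 0.305 ± 0.291 CPM) and MSTN (5.17 ± 0.46) rose. DES, the muscle intermediate filament desmin (-3.65 ± 0.75, 3.70 ± 0.366 against 46.5 ± 0.711 CPM), and the limb factors SHOX2 (-2.52 ± 0.49) and SHOX (-2.75 ± 0.29) fell. FOS rose to 459.5 ± 7.21 CPM (4.26 ± 0.30), a level below that of the other HOX groups (-1.58 ± 0.23). Limb patterning factors gave 1 rise and 19 falls among 47, with 1 and 20 adjusted over the list alone (camera: lower, adjusted p = 0.00771, or 0.335 estimated). Skeletal muscle genes gave 0 and 18 among 35, with 0 and 23 (lower, adjusted p = 8.97e-07, or 0.696 estimated). Of smooth muscle and contractile genes, 1 of 14 rose, 7 fell and 6 did not pass, against 1 higher and 8 lower adjusted over the list alone (lower, adjusted p = 0.0134, or 0.805 estimated, and 0.0563 without HOXA9 replicate 1, 0.225 without Ctrl replicate 2, 0.077 with the series term and 0.325 without series 38). LMOD1 (-2.65 ± 0.41) was among the falls. In all, 5231 genes passed the test, 2209 higher and 3022 lower. The count was 2640 without HOXA9 replicate 1 and 3015 without HOXA9 replicate 2.

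Set against the other HOX groups (n = 2 against n = 16), HOXA9 cultures had lower Id1 (-4.38 ± 0.36, 11.4 ± 3.82 against 244 ± 73.9 CPM) and ID3 (-2.01 ± 0.21), targets of BMP signalling, and lower CHRD (-1.56 ± 0.18), the BMP antagonist chordin. The limb factors SHOX2 (-2.41 ± 0.42, 1.24 ± 0.174 against 6.89 ± 2.54 CPM), TBX2 (-2.58 ± 0.27), MSX1 (-2.34 ± 0.25) and DLX6 (-2.41 ± 0.30) fell with 29 of 47 limb patterning factors, against 1 that rose and 17 that did not pass. Adjusted over the list alone, 30 fell and 2 rose (adjusted p = 6.16e-07, or 0.226 estimated). BMP and GDF signalling genes gave 3 rises and 9 falls among 27, with 3 and 11 adjusted over the list alone (lower, adjusted p = 0.0461, or 0.74 estimated, and 0.0507 without HOXA13 replicate 2, 0.0533 without HOXD12 replicate 1 and 0.0772 with the series term). Immediate early and heat shock genes gave 1 rise and 10 falls among 21, as over the list alone (lower, adjusted p = 0.0246, or 0.838 estimated). IER5 (-3.41 ± 0.35) had the largest fall in that list. The cartilage proteoglycan gene EPYC (2.85 ± 0.51, 221 ± 78.9 against 40.2 ± 35.3 CPM) and angiotensinogen (AGT, 1.42 ± 0.20) rose, and the replication licensing gene CDC6 (-3.51 ± 0.32) and the class I MHC gene BFIV21 (-2.04 ± 0.25) fell. In all, 6846 genes passed the test, 3273 higher and 3573 lower. The count was 3416 without HOXA9 replicate 1 and 3985 without HOXA9 replicate 2. No other group has libraries of series 122, so no value within a series can be given for HOXA9.

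**Figure D3:**
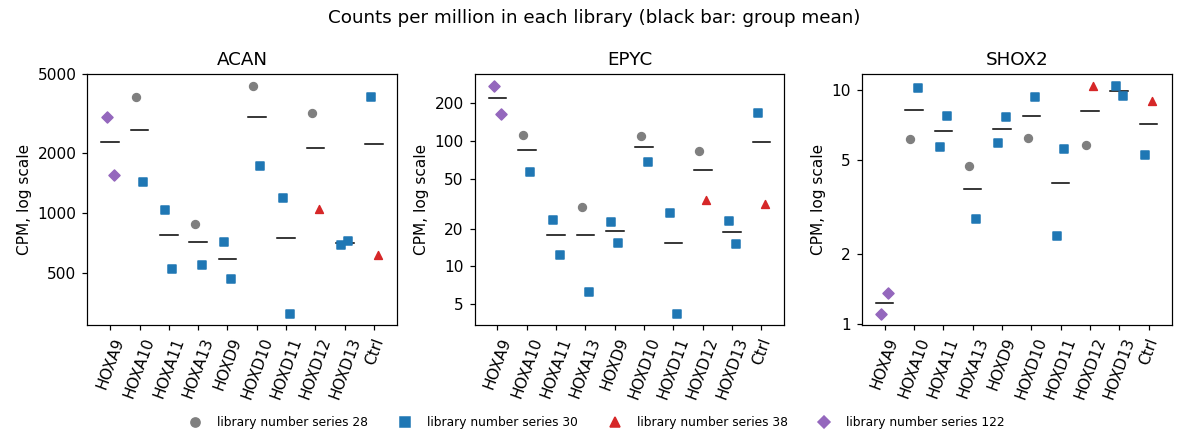
CPM of the cartilage genes ACAN and EPYC and of the limb factor SHOX2 on a log axis in each library (points, shaped and coloured by library number series), with the group mean as a black bar. SHOX2 lay at 1.11 and 1.36 CPM in the HOXA9 libraries and at 2.37 CPM or above elsewhere, while ACAN ran from 619 to 3838 CPM between the Ctrl libraries alone.

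Cultures with HOXA13, which patterns the hand and foot plate, had the next highest number of called genes. Against Ctrl, the WNT receptor FZD10 rose from 0.558 ± 0.159 to 18.8 ± 12.2 CPM (5.03 ± 0.43, adjusted p = 8.02e-06) and MMP13 from 23.4 ± 4.16 to 384 ± 186 CPM (4.03 ± 0.34). The osteoblast factor RUNX2 (2.04 ± 0.38) rose, and COL3A1 (-1.67 ± 0.27), the leukocyte phosphatase PTPRC (-1.99 ± 0.38) and MEIS1 (-1.52 ± 0.29) fell. Proliferation genes gave 22 rises and 0 falls among 41, with 30 and 0 adjusted over the list alone (camera: higher, adjusted p = 1.73e-11, or 0.247 estimated). CCNB2 (0.84 ± 0.11), PLK1 (0.79 ± 0.12) and CDC20 (0.83 ± 0.12) were among the rises. Limb patterning factors gave 22 and 5 among 47, with 25 and 6 (higher, adjusted p = 0.000173, or 0.217 estimated). WNT signalling genes gave 11 and 2 among 28, with 12 and 4 (higher, adjusted p = 0.00849, or 0.217 estimated). Skeletal muscle genes were lower as a list, with 7 falling and 1 rising, and 7 and 1 adjusted over the list alone (adjusted p = 1.05e-06, or 0.696 estimated, and 0.0549 without HOXA13 replicate 2), and the 2 HOXA13 libraries were a median of 2.884 apart in it on the log2 scale, replicate 2 lower. In all, 3744 genes passed the test, 1853 higher and 1891 lower; with series 30 alone, 1 library on each side, the count was 5025.

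The same factor set against the other HOX groups had a higher vasopressin receptor AVPR1A (5.90 ± 0.21, 53.2 ± 17.4 against 2.13 ± 2.52 CPM), the limb factor EN1 (4.42 ± 0.39, 8.31 ± 4.82 against 0.446 ± 0.325 CPM), the R-spondin receptor LGR5 (2.26 ± 0.14) and FZD10 (3.40 ± 0.21). The fat cell receptor PPARG (-2.05 ± 0.21, 2.59 ± 0.344 against 11.5 ± 4.76 CPM), tenomodulin (TNMD, -1.01 ± 0.14), asparagine synthetase (ASNS, -0.88 ± 0.10) and the globin gene HBE (-2.93 ± 0.45) fell. Proliferation genes gave 32 rises and 0 falls among 41, with 37 and 0 adjusted over the list alone (higher, adjusted p = 9.87e-18, or 0.226 estimated). Unfolded protein and amino acid stress genes gave 0 and 6 among 21, with 0 and 6 (lower, adjusted p = 4.36e-05, or 0.226 estimated). Hypoxia and glycolysis genes were lower too (adjusted p = 0.00683, or 0.855 estimated, and 0.794 without HOXA13 replicate 2), with 3 of 25 falling and 1 adjusted over the list alone. Markers of blood and macrophages gave 0 rises and 4 falls among 27, with 2 and 11 adjusted over the list alone (lower, adjusted p = 0.00537, or 0.775 estimated, and 0.245 without HOXA13 replicate 2). Fat markers gave 1 and 4 among 12, with 1 and 5 (lower, adjusted p = 0.0347, or 0.322 estimated, and 0.0705 without HOXA13 replicate 1 and 0.0814 without HOXA13 replicate 2). In all, 3240 genes passed the test, 1891 higher and 1349 lower, and the count was 1977 without HOXA13 replicate 2.

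**Figure D4:**
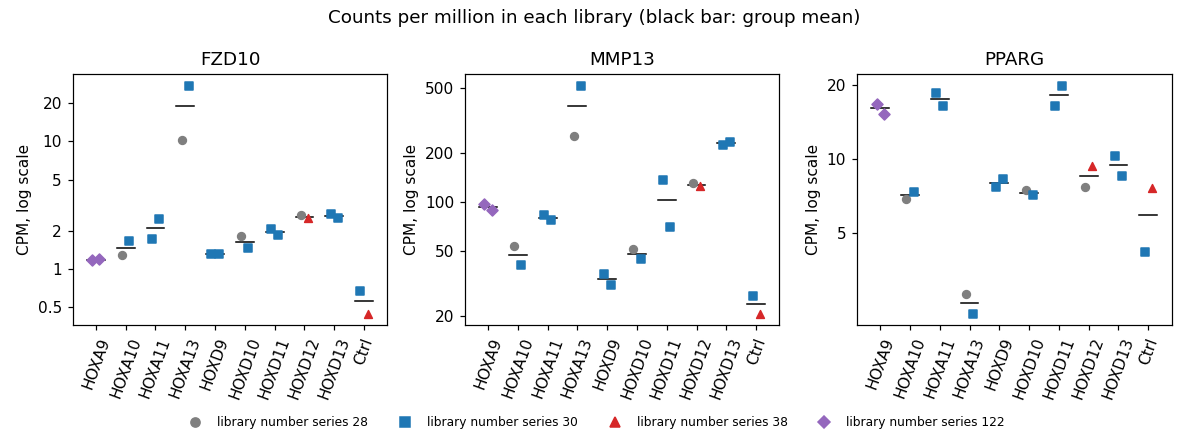
CPM of FZD10, MMP13 and PPARG on a log axis in each library (points, shaped and coloured by library number series), with the group mean as a black bar. FZD10 lay at 10.2 and 27.4 CPM in the HOXA13 libraries and at 2.68 CPM or below in all others, while PPARG was lowest in the HOXA13 libraries at 2.83 and 2.34 CPM.

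In HOXA10 cultures, FOS was at 1391 ± 29.6 CPM, higher than in Ctrl (5.86 ± 0.33), as were WNT16 (4.14 ± 0.59), MSTN (4.07 ± 0.44) and the tendon genes TNMD (1.41 ± 0.18) and COL1A2 (1.11 ± 0.17). HOXD10 cultures had FOS at 1912 ± 430.0 CPM (6.32 ± 0.33 against Ctrl), with higher levels of the orphan nuclear receptors NR4A2 (4.60 ± 0.60) and NR4A3 (4.20 ± 0.64), of WNT16 (4.07 ± 0.59) and of TNMD (1.26 ± 0.18). ADAMTS8 (-2.15 ± 0.17) was lower. Of tendon and fibrous connective tissue genes, 4 of 24 rose, 0 fell and 20 did not pass, against 6 higher and 0 lower adjusted over the list alone with HOXA10 (camera: higher, adjusted p = 0.00534, or 0.538 estimated, and 0.0538 without HOXA10 replicate 2 and 0.252 without Ctrl replicate 1). With HOXD10, 4 of 24 rose, 0 fell and 20 did not pass, against 7 higher and 0 lower adjusted over the list alone (higher, adjusted p = 0.0108, or 0.61 estimated, and 0.0776 without HOXD10 replicate 2 and 0.366 without Ctrl replicate 1). With HOXA10, 734 genes passed the test, 429 higher and 305 lower, and 153 without HOXA10 replicate 1 and 311 without HOXA10 replicate 2. With HOXD10, 804 genes passed the test, 476 higher and 328 lower, and 221 without HOXD10 replicate 1 and 230 without HOXD10 replicate 2, and 1310 passed within series 30, where HOXA10 had 1012.

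Against the other HOX groups, 80 genes passed the test, 63 higher and 17 lower for HOXA10, and 58 genes passed the test, 51 higher and 7 lower for HOXD10. The tendon gene TNMD was higher in both (0.96 ± 0.12 and 0.79 ± 0.12). Without HOXA10 replicate 1 it was at 0.82 ± 0.16 for HOXA10 (adjusted p = 0.287, over a range of 8.29e-09 to 0.287). For HOXD10 it was at 0.75 ± 0.17 and 0.83 ± 0.17 without HOXD10 replicate 1 or 2 (adjusted p = 0.479 and 0.226, over a range of 1.78e-05 to 0.479), so these calls were lost at similar folds and larger SEs. Cartilage matrix genes were higher as a list in both, although 0 of 28 members passed the test over all genes (adjusted p = 5.79e-06, or 0.775 estimated, and 0.143 without HOXA10 replicate 1 for HOXA10, and adjusted p = 9.42e-07, or 0.775 estimated, and 0.0512 without HOXD10 replicate 1 for HOXD10). Adjusted over the list alone, 0 members rose for HOXA10 and 0 for HOXD10. The 2 libraries of a group differed in this list by a median of 1.14 (HOXA10) and 0.998 (HOXD10) on the log2 scale, and ACAN ran from 3832 CPM in HOXA10 replicate 1 to 1440.0 in replicate 2 and from 4387 to 1725 in the HOXD10 replicates. Markers of neural crest, glia and pigment gave 1 rise among 15, and 4 adjusted over the list alone, for HOXA10 (higher, adjusted p = 0.00457, or 0.226 estimated). The HOXA10 count was 1 without HOXA10 replicate 1, 10 without HOXA10 replicate 2, 53 without HOXA11 replicate 1 and 205 without HOXA13 replicate 1. It was 137 without HOXA13 replicate 2, 48 without HOXD9 replicate 1, 50 without HOXD9 replicate 2 and 46 without HOXD13 replicate 2, and 95 within series 30. The HOXD10 count was 35 without HOXA10 replicate 2, 33 without HOXA11 replicate 2, 128 without HOXA13 replicate 1, 30 without HOXD9 replicate 1, 25 without HOXD9 replicate 2 and 3 without HOXD10 replicate 1. It was 3 without HOXD10 replicate 2, 38 without HOXD11 replicate 1, 26 without HOXD11 replicate 2, 27 without HOXD12 replicate 2, 34 without HOXD13 replicate 1 and 24 without HOXD13 replicate 2, and 123 within series 30.

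Cultures with HOXA11 or HOXD11, which pattern the forearm, both had a higher level of the anion exchanger gene SLC26A7 than Ctrl (4.06 ± 0.46, 14.3 ± 3.01 against 0.861 ± 0.0436 CPM for HOXA11, and 3.67 ± 0.46 for HOXD11). Both also had higher levels of the VEGF receptor FLT4 (2.23 ± 0.32 and 1.88 ± 0.32), PPARG (1.58 ± 0.23 and 1.63 ± 0.23) and the guidance receptor PLXNA2 (1.76 ± 0.21 and 1.73 ± 0.21). The growth factor gene RSPO2 (1.92 ± 0.26) was higher and MMP9 (-2.94 ± 0.43) lower in HOXA11 cultures, and the peptidase ENPEP (3.34 ± 0.41) was higher and SEMA5A (-0.81 ± 0.12) lower in HOXD11 cultures. Of ectoderm and epithelium markers, 2 of 22 rose, 0 fell and 20 did not pass, against 6 higher and 0 lower adjusted over the list alone with HOXD11 (camera: higher, adjusted p = 0.000313, or 0.707 estimated, and 0.0949 without HOXD11 replicate 2 and 0.0708 within series 30). Cartilage matrix genes were lower as lists with 0 members passing over all genes and 0 and 0 falling adjusted over the list alone (adjusted p = 0.000371, or 0.805 estimated, and 0.587 without Ctrl replicate 1 for HOXA11, and adjusted p = 1.25e-05, or 0.746 estimated, and 0.0718 without HOXD11 replicate 2 and 0.204 without Ctrl replicate 1 for HOXD11). In this list the replicates differed by a median of 0.531 (HOXA11), 1.43 (HOXD11) and 1.77 (Ctrl) on the log2 scale. With HOXA11, 995 genes passed the test, 622 higher and 373 lower. The count was 294 without HOXA11 replicate 1 and 246 without HOXA11 replicate 2, and 2844 within series 30. With HOXD11, 877 genes passed the test, 503 higher and 374 lower. The count was 342 without HOXD11 replicate 1, 204 without HOXD11 replicate 2 and 519 without Ctrl replicate 1, and 3082 within series 30, where Ctrl has 1 library.

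Set against the other HOX groups, HOXA11 cultures had higher neuropeptide Y (NPY, 2.60 ± 0.24, 11.2 ± 0.623 against 2.24 ± 1.51 CPM), the receptor kinase LTK (2.22 ± 0.21), FLT4 (1.92 ± 0.19) and the retinoic acid binding protein CRABP1 (0.91 ± 0.09). HOXD11 cultures had higher LTK (1.96 ± 0.21) and the WNT antagonist Dkk-1 (2.15 ± 0.23, 13.6 ± 4.53 against 4.33 ± 3.18 CPM), and lower MSTN (-3.10 ± 0.36) and SEMA5A (-1.32 ± 0.10). For HOXA11, 154 genes passed the test, 131 higher and 23 lower. The count was 25 without HOXA11 replicate 1, 20 without HOXA11 replicate 2, 236 without HOXA13 replicate 1 and 99 without HOXD13 replicate 2, and 432 within series 30. For HOXD11, 193 genes passed the test, 113 higher and 80 lower. The count was 293 without HOXA13 replicate 1, 346 without HOXA13 replicate 2 and 119 without HOXD9 replicate 1. It was 34 without HOXD11 replicate 1, 11 without HOXD11 replicate 2, 125 without HOXD13 replicate 1 and 122 without HOXD13 replicate 2, and 519 within series 30.

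HOXD9 cultures had FOS at 1343 ± 362 CPM, higher than in Ctrl (5.81 ± 0.33), and higher EGR1 (3.42 ± 0.34), MSTN (4.75 ± 0.45), the BMP regulator BMPER (1.96 ± 0.25) and the adrenergic receptor ADRA2C (3.37 ± 0.28). CRABP1 (-1.03 ± 0.14) and OAS*A (-2.95 ± 0.36) were lower. Immediate early and heat shock genes gave 8 rises and 0 falls among 21, with 9 and 0 adjusted over the list alone (camera: higher, adjusted p = 2.05e-11, or 0.277 estimated). Cholesterol and lipid synthesis genes were lower as a list, with 0 rising and 3 falling, and 3 falling adjusted over the list alone (adjusted p = 1.28e-06, or 0.635 estimated). In all, 1112 genes passed the test, 612 higher and 500 lower. The count was 284 without HOXD9 replicate 1, 173 without HOXD9 replicate 2 and 631 without Ctrl replicate 1, and 3378 within series 30. Set beside the other HOX groups, the adrenergic receptor ADRA2A (2.22 ± 0.18) rose and LRRN2 (-2.83 ± 0.28) fell. Hypertrophy and bone genes were lower as a list, with 1 falling and 0 rising, and 12 and 1 adjusted over the list alone (adjusted p = 1.37e-05, or 0.52 estimated). In that comparison, 295 genes passed the test, 215 higher and 80 lower. The count was 45 without HOXD9 replicate 1 and 10 without HOXD9 replicate 2, and 1021 within series 30.

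FOS in HOXD12 cultures was at 1811 ± 435 CPM, higher than in Ctrl (6.24 ± 0.33), as were NR4A2 (4.90 ± 0.61), NR4A3 (4.51 ± 0.65), MMP13 (2.44 ± 0.32) and ID3 (1.42 ± 0.24), while the secreted peptide gene SCG2 (-2.11 ± 0.31) was lower. Limb patterning factors gave 9 rises and 0 falls among 47, with 11 and 1 adjusted over the list alone (camera: higher, adjusted p = 1.62e-05, or 0.179 estimated). WNT signalling genes gave 7 and 0 among 28, with 10 and 0 (higher, adjusted p = 0.000625, or 0.179 estimated). Of cell adhesion and axon guidance genes, 10 of 45 rose, 1 fell and 34 did not pass, against 12 higher and 3 lower adjusted over the list alone (higher, adjusted p = 0.0133, or 0.424 estimated, and 0.0543 without HOXD12 replicate 2 and 0.306 without Ctrl replicate 1). In all, 770 genes passed the test, 501 higher and 269 lower. The count was 301 without HOXD12 replicate 1 and 305 without HOXD12 replicate 2. Without both series 38 libraries, the pair rich in unnamed loci, it was 243. In contrast with the other HOX groups, the guidance ligand SLIT2 was higher (1.01 ± 0.09, 95.1 ± 0.531 against 49.6 ± 17.7 CPM). Skeletal muscle genes were higher as a list with 0 members passing over all genes and 1 adjusted over the list alone (adjusted p = 5.86e-10, or 0.666 estimated), in a list where the HOXA13 and HOXD11 libraries on the other side were a median of 2.884 and 1.552 apart. In that comparison, 174 genes passed the test, 155 higher and 19 lower, but 12 with series as a term and 27 without the series 38 libraries. Leaving out single libraries gave 113 without HOXA9 replicate 1, 112 without HOXA9 replicate 2, 104 without HOXA11 replicate 1, 95 without HOXA11 replicate 2 and 427 without HOXA13 replicate 1. It was 282 without HOXA13 replicate 2, 104 without HOXD9 replicate 1, 112 without HOXD10 replicate 2, 72 without HOXD12 replicate 1, 17 without HOXD12 replicate 2 and 77 without HOXD13 replicate 1. HOXD12 has no pair of libraries within 1 series.

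Against Ctrl, HOXD13 cultures had higher FOS, at 1391 ± 456 CPM (5.86 ± 0.33), and higher levels of the stromelysin gene MMP10 (4.45 ± 0.67, 52.3 ± 12.2 against 2.48 ± 2.24 CPM), MMP13 (3.28 ± 0.33), MSX1 (1.68 ± 0.27), BMP7 (1.71 ± 0.26) and the BMP pseudoreceptor BAMBI (1.21 ± 0.20). The kinase gene SRC (-2.63 ± 0.30) fell. BMP and GDF signalling genes gave 4 rises and 0 falls among 27, with 7 and 1 adjusted over the list alone (camera: higher, adjusted p = 0.00102, or 0.378 estimated). Of FGF signalling genes, 2 of 21 rose, 0 fell and 19 did not pass, against 2 higher and 0 lower adjusted over the list alone (higher, adjusted p = 0.0108, or 0.678 estimated, and 0.991 without Ctrl replicate 1). In all, 715 genes passed the test, 422 higher and 293 lower. The count was 192 without HOXD13 replicate 1, 154 without HOXD13 replicate 2 and 470 without Ctrl replicate 1, and 2393 within series 30. Relative to the other HOX groups, MMP10 was higher (3.23 ± 0.34, adjusted p = 0.000789). Without HOXD13 replicate 2 it was at 2.98 ± 0.45 (adjusted p = 0.0835, over a range of 1.24e-10 to 0.0835). Interferon and antiviral genes were higher as a list, with 1 rising and 0 falling, and 3 and 0 adjusted over the list alone (adjusted p = 0.00165, or 0.738 estimated, and 0.0727 within series 30). In that comparison, 145 genes passed the test, 88 higher and 57 lower. The count was 91 without HOXA10 replicate 1, 83 without HOXA11 replicate 1, 83 without HOXA11 replicate 2, 239 without HOXA13 replicate 1 and 250 without HOXA13 replicate 2. It was 84 without HOXD9 replicate 1, 91 without HOXD9 replicate 2, 96 without HOXD10 replicate 2, 4 without HOXD13 replicate 1 and 0 without HOXD13 replicate 2, and 516 within series 30. At the count of 0, 869 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 over all libraries called 379.

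The design also set same-number genes of the HOXA and HOXD clusters against each other. HOXA9 cultures differed from HOXD9 cultures in 22 lower and 0 higher limb patterning factors of 47, with 24 and 1 adjusted over the list alone (camera: lower, adjusted p = 6.97e-05, or 0.193 estimated). Among them were SHOX2 (-2.45 ± 0.49), TBX2 (-2.03 ± 0.30) and MSX1 (-2.04 ± 0.28). ADGRG7 (3.55 ± 0.41) and BMP6 (1.38 ± 0.17) were higher and Id1 (-4.24 ± 0.38) and HAND1 (-4.08 ± 0.31) lower in HOXA9. Cartilage matrix genes were higher, 8 of 28 passing upwards and 0 downwards, with 8 and 1 adjusted over the list alone (adjusted p = 0.00016, or 0.885 estimated), and the replicates differed in it by a median of 0.869 (HOXA9) and 0.372 (HOXD9). In all, 4167 genes passed the test, 1618 higher and 2549 lower. The count was 1542 without HOXA9 replicate 1, 2458 without HOXA9 replicate 2, 2654 without HOXD9 replicate 1 and 1289 without HOXD9 replicate 2. In both groups 690 genes differed from Ctrl, 672 in the same direction and 18 in opposite directions, where independent lists would share 156. At an unadjusted p under 0.05 the groups shared 1965 in the same direction, against a simulated mean of 183. Over called genes, 20 simulations of unchanged groups against the same controls gave 0, a value fixed by their near lack of calls.

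Between HOXA13 and HOXD13, AVPR1A (3.82 ± 0.39), FBLN1 (1.95 ± 0.31), LGR5 (1.54 ± 0.23) and FZD10 (2.85 ± 0.38) were higher in HOXA13. COL3A1 (-1.53 ± 0.27), PPARG (-1.86 ± 0.25), ASNS (-0.99 ± 0.13) and the protease gene PLAU (-3.25 ± 0.31) were lower. Proliferation genes gave 15 rises and 0 falls among 41, with 29 and 0 adjusted over the list alone (camera: higher, adjusted p = 1.75e-18, or 0.193 estimated). In all, 1101 genes passed the test, 557 higher and 544 lower. The count was 345 without HOXD13 replicate 1 and 265 without HOXD13 replicate 2, and 2237 within series 30. In both, 565 genes differed from Ctrl, 563 of them in the same direction, where independent lists would share 73. The 20 simulations gave 0, a value fixed by their near lack of calls. At an unadjusted p under 0.05 the groups shared 2344 in the same direction, against a simulated mean of 190. Part of this overlap may come from the shared controls.

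HOXA10 and HOXD10 were not separated by any gene: edgeR called 0 and DESeq2 0, with 213 genes at an unadjusted p under 0.05, and edgeR called 0 within series 30 (334 unadjusted). Shared changes against Ctrl numbered 536, all in the same direction, where independent lists would share 16.6 and the 20 simulations gave 0. At an unadjusted p under 0.05 they shared 2694 in the same direction, against a simulated mean of 194. As a list, immediate early and heat shock genes were lower in HOXA10 although 0 members passed the test (adjusted p = 1e-12, or 0.354 estimated). HOXA11 and HOXD11 differed in 1 gene, listed as K123 (3.35 ± 0.39, adjusted p = 0.0113, 6.97 ± 0.977 against 0.662 ± 0.341 CPM), with 460 genes at an unadjusted p under 0.05. In edgeR 0 genes passed without HOXA11 replicate 1 or 2 or HOXD11 replicate 1 (309, 389 and 262 at an unadjusted p under 0.05), 3 passed without HOXD11 replicate 2 and 5 within series 30, and DESeq2 over all libraries called 13. Without these libraries, K123 was at 3.20 ± 0.44, 3.48 ± 0.44 and 2.94 ± 0.45 (adjusted p = 0.145, 0.0557 and 0.35, over a range of 2.03e-12 to 0.35), so the call was lost at a similar fold and a larger SE. HOXA11 and HOXD11 shared 609 changes against Ctrl, all in the same direction, where independent lists would share 24.7 and the 20 simulations gave 0. At an unadjusted p under 0.05 they shared 2628 in the same direction, against a simulated mean of 191. A lack of calls does not show that these factors act alike, and part of each overlap may come from the shared controls.

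Over the whole profile, the 4 same-number pairs lay at a mean distance of 0.5404 (root mean square difference of log2 CPM group means). All 24 matchings of HOXA with HOXD groups averaged 0.6286. The real matching ranked 1 of 24 in the exact one-sided permutation test, p = 0.04167, the smallest it can give, and without HOXD11 replicate 2 p was 0.08333. Within series 30 it ranked 1 of 6 (0.5203 against 0.5913), where the smallest possible p is 0.167. Among the 36 pairs of HOX groups, the fewest genes separated HOXA10 from HOXD10 (0) and HOXA11 from HOXD11 (1), and the most separated HOXA9 from HOXA13 (6378). Any difference among the 9 HOX groups was found in 5087 genes, 2346 without HOXA9 replicate 1 and 2787 without HOXA9 replicate 2, and in 2502 within series 30.

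The distal factors HOXA13 and HOXD13 were then set against the 6 groups of numbers 9 to 11 (n = 4 against n = 12). MMP13 (2.25 ± 0.16, 306 ± 140.4 against 67.3 ± 30.5 CPM), MSX1 (1.08 ± 0.15), LGR5 (1.60 ± 0.12), LEF1 (1.28 ± 0.19), a transcription factor of WNT signalling, and BMP7 (0.91 ± 0.14) were higher. ASNS (-0.40 ± 0.08), PSAT1 (-0.51 ± 0.09) and the growth factor gene FGF19 (-2.72 ± 0.48, 0.579 ± 0.397 against 4.05 ± 1.85 CPM) were lower. The HOXD13 libraries lay inside the range of the 12 libraries of numbers 9 to 11 for ASNS (407.5 and 363.3 CPM) and for PSAT1. Of proliferation genes, 18 of 41 rose, 0 fell and 23 did not pass, against 28 higher and 0 lower adjusted over the list alone (camera: higher, adjusted p = 1.21e-11, or 0.115 estimated). Limb patterning factors gave 18 rises and 2 falls among 47, with 22 and 3 over the list alone (higher, adjusted p = 1.33e-05, or 0.115 estimated). Unfolded protein and amino acid stress genes gave 0 and 7 among 21, with 1 and 7 over the list alone (lower, adjusted p = 0.00302, or 0.215 estimated). List medians on the log2 scale, against the mean of all libraries, set HOXA13 apart for proliferation (0.359 and 0.575) and for this stress list (-0.237 and -0.471). The HOXD13 libraries lay inside the range of numbers 9 to 11 in both (-0.006 and -0.042, and 0.12 and -0.011). These 2 list results therefore do not show a trait shared by HOXA13 and HOXD13. In all, 2380 genes passed the test, 1323 higher and 1057 lower. The count was 1141 without HOXD13 replicate 1 and 1120 without HOXD13 replicate 2 and 3845 with series as a term; with series 30 alone this comparison has no value because no HOXA9 library is in that series.

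A split of the factors by where they bind the genome was taken from knowledge of the study. Its membership was not checked, because no table used here gives binding. HOXA11, HOXD11 and HOXD13 (binding group 2, n = 6) were set against the other 6 (binding group 1, n = 12). All 6 libraries of group 2 are of series 30, which holds 5 of the 12 of group 1, so the sets are partly confounded with the series. FLT4 (1.17 ± 0.15), LTK (1.81 ± 0.16), PPARG (0.99 ± 0.11), the stem cell factor receptor KIT (1.75 ± 0.20) and SLIT2 (0.67 ± 0.07) were higher. The serotonin receptor HTR7 (-1.74 ± 0.21), the WNT inhibitor APCDD1 (-0.94 ± 0.16) and SEMA5A (-0.72 ± 0.06) were lower. The HOXD13 libraries lay inside the range of binding group 1 for FLT4 (3.23 and 4.98 CPM), LTK (3.43 and 3.77), PPARG (10.3 and 8.56) and SEMA5A (782.9 and 789.2). For SLIT2 (57.6 to 87.8 CPM in binding group 2), HOXD12, in binding group 1, lay above all 6 binding group 2 libraries (94.8 and 95.5), and the lower HOXD13 library was at 57.6. Cartilage matrix genes were lower as a list, with 1 of 28 falling over all genes and 12 falling adjusted over the list alone (adjusted p = 1.58e-08, or 0.567 estimated; within series 30, 0.0128), the list that differed with series and replicate number, by medians of 0.366 to 1.43 between replicates in group 2 and 0.372 to 1.32 in group 1. Endothelium markers gave 2 rises and 0 falls among 17, with 6 and 1 adjusted over the list alone (higher, adjusted p = 0.0109, or 0.115 estimated, and 0.0732 within series 30). In all, 993 genes passed the test, 500 higher and 493 lower. The count was 650 without HOXA9 replicate 1, 610 without HOXA11 replicate 1, 375 without HOXA11 replicate 2 and 625 without HOXD9 replicate 1. It was 627 without HOXD11 replicate 1, 539 without HOXD11 replicate 2, 469 without HOXD13 replicate 1 and 452 without HOXD13 replicate 2, 447 with HOXA9 left out and 1144 within series 30, 559 of them among the 993. The mean distance between groups of different binding sets minus that within sets was below 0 (difference -0.04221, rank 53 of 84 splits, exact one-sided permutation p = 0.631).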

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

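The tests of library number series, of replicate number, of infection without a HOX gene and of spread between libraries, and the counts over other splits of the groups, were chosen only after the results were seen. The test of sequencing depth was written before its result was seen.

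A few genes moved in opposite directions against Ctrl in groups of the same number, each with a called difference between the groups in edgeR's quasi-likelihood test. The mesoderm factor HAND1 was lower with HOXA9 (-3.0 ± 0.31, adjusted p = 3.69e-05) and higher with HOXD9 (1.08 ± 0.25, adjusted p = 0.0239), a difference of -4.08 ± 0.31 (adjusted p = 6.12e-06). The WNT antagonist Dkk-1 was at -2.64 ± 0.44 (adjusted p = 0.000879) with HOXA9 and 1.33 ± 0.36 (adjusted p = 0.0451) with HOXD9, a difference of -3.97 ± 0.44 (adjusted p = 9.01e-05). The microRNA gene MIR3523, with few counts in HOXA9, was at -2.46 ± 0.75 (adjusted p = 0.0261) and 2.63 ± 0.55 (adjusted p = 0.0142), a difference of -5.09 ± 0.70 (adjusted p = 0.000355). The protease gene PLAU was lower with HOXA13 (-2.06 ± 0.31, adjusted p = 0.000552) and higher with HOXD13 (1.19 ± 0.28, adjusted p = 0.0308), a difference of -3.25 ± 0.31 (adjusted p = 0.000136). The proteoglycan gene BCAN was at -0.97 ± 0.20 (adjusted p = 0.00462) and 0.88 ± 0.19 (adjusted p = 0.0236), a difference of -1.85 ± 0.20 (adjusted p = 0.000252). The differences between the groups held with each library left out, and the calls against Ctrl of HAND1, Dkk-1, PLAU and BCAN with HOXA9 or HOXA13 did too. The other calls against Ctrl were lost with single libraries left out, each with its direction kept, its log2 fold change moved by less than 1.5 times and a larger SE. HAND1 with HOXD9 was at 1.27 ± 0.29, 0.87 ± 0.30 and 0.99 ± 0.32 (adjusted p = 0.0549, 0.226 and 0.122) without HOXD9 replicate 1, HOXD9 replicate 2 or Ctrl replicate 1 (0.00104 to 0.226 over all alternatives). Dkk-1 with HOXD9 was at 1.45 ± 0.44, 1.23 ± 0.44, 1.48 ± 0.48 and 1.22 ± 0.46 (adjusted p = 0.124, 0.255, 0.116 and 0.125) without HOXD9 replicate 1, HOXD9 replicate 2, Ctrl replicate 1 or Ctrl replicate 2 (0.00514 to 0.255). MIR3523 with HOXA9 was at -2.30 ± 1.00, -2.63 ± 1.03 and -1.74 ± 0.86 (adjusted p = 0.14, 0.1 and 0.174) without HOXA9 replicate 1, HOXA9 replicate 2 or Ctrl replicate 2 (0.00161 to 0.174). With HOXD9 it was at 2.12 ± 0.60 and 2.10 ± 0.66 (adjusted p = 0.144 and 0.109) without HOXD9 replicate 2 or Ctrl replicate 1 (6.05e-05 to 0.144). PLAU with HOXD13 was at 1.27 ± 0.34, 1.13 ± 0.34, 1.07 ± 0.36 and 1.33 ± 0.36 (adjusted p = 0.11, 0.177, 0.142 and 0.0547) without HOXD13 replicate 1, HOXD13 replicate 2, Ctrl replicate 1 or Ctrl replicate 2 (0.00206 to 0.177). Without the same libraries BCAN was at 1.02 ± 0.23, 0.73 ± 0.24, 0.82 ± 0.25 and 0.95 ± 0.25 (adjusted p = 0.0617, 0.214, 0.111 and 0.0522, over 0.00177 to 0.214). Such genes numbered 18 for HOXA9 and HOXD9, 2 for HOXA13 and HOXD13 and 0 for the pairs of numbers 10 and 11.

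HOXA9 differed from the other HOX groups in 6846 genes and from Ctrl in 5231, more than any other group. Lower sequencing depth is argued against: with every library thinned to the same total, 6362 genes were called for HOXA9 and 2753 for HOXA13, the next highest. Both HOXA9 libraries are alone in series 122, and 11 genes lay under 0.5 CPM in both and at 3 CPM or more in all 18 others, a pattern found for 0 genes in any other group. These genes were mostly loci without a name, with a U6 RNA row. U6 rows were among the largest falls against HOXD9 (-7.17 ± 0.61, -3.96 ± 0.34 and -3.90 ± 0.34). The series and the HOXA9 gene cannot be told apart by these values, because no HOXA9 library belongs to another series. Either may account for the response, so the HOXA9 counts are best read as those of 2 libraries of their own series.

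Of 21 immediate early and heat shock genes, 7 rose in the HOX groups over Ctrl and 14 did not pass, with a median log2 fold change of 2.57 for the 7 and 0.42 for the whole list, whose call was lost with an estimated correlation (adjusted p = 0.378). Within series 30 (11 HOX libraries of 7 groups and 1 Ctrl library) the median of the 7 was 2.97 and of the list 1.34. The 7 thus rose within 1 series, but were picked over libraries that include these. That Ctrl library had the lower list median (-1.078, against -0.09 in Ctrl replicate 2), so both values rest on it. Infection itself, or handling shared by the infected cultures, may account for the rise, and the number of groups labelled as infected without a HOX gene that could test this is 0. The HOX genes and the virus therefore cannot be told apart here.

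The list of 28 cartilage matrix genes was higher in replicate 1 than in replicate 2 in 10 of 10 groups, the 5 of a single series included (exact two-sided sign test p = 0.00195, the smallest it can give). General spread between libraries stays open, since the list was picked for this pattern and its median absolute difference was above that of each of the other 23 lists in 3 of 10 groups (HOXA10, HOXD12 and Ctrl). That difference was larger in the 5 groups whose libraries come from different series (mean 1.23 on the log2 scale) than in the 5 of a single series (0.713), with exact one-sided p = 0.0397 over 252 splits, where the smallest possible p is 0.00397. The series may thus be 1 source, although HOXD11, with both libraries in series 30, differed by 1.43. A condition that follows the replicate number, which the labels do not describe, may be another: of the other 23 lists, only interferon and antiviral genes, lower in replicate 1 (medians of -0.007 to -0.528), kept 1 sign in all groups, markers of blood and macrophages were lower in replicate 1 in 8 of 10 groups, with medians of -1.021 to -1.437 in HOXA9, HOXA10, HOXD10, HOXD12 and Ctrl, and what that condition is stays open, with no biological explanation tested.

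Chance could not be excluded for the sets of groups compared. For HOXA13 and HOXD13 against numbers 9 to 11, 8 of the 28 splits of whole groups gave at least the real count of 2380 genes, and the highest other split gave 4823. For the binding groups, 43 of 84 splits gave at least the real 993, and the highest other gave 4006. The highest splits were those with HOXA9 in the smaller set, which points to a structure of the samples: without them the highest other counts were 1780 and 2417, and, with the real split counted, 1 of 21 (the real split alone) and 15 of 56 gave as many.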

How the results depend on the processing

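The fits with a series term, with series 30 alone, without HOXA9 and without both series 38 libraries, the losses counted over all calls and the test of replicate numbering were chosen only after the results were seen. In 270 recomputed values of 30 results, single libraries left out aside, 184 stayed within 1.5 times the reported count or on their side of the threshold, and 86 did not. A like count can hold other genes: without series 38, HOXA10 against Ctrl had 593 calls, which shared 346 with the reported 734, and all HOX groups against Ctrl had 1876, which shared 1163 with the reported 2308. RLE scaling, no filter on low counts and leaving HOX genes out moved 0 of 27 counts each by over 1.5 times. The cause of the moves below was not tested, except that fits on fewer libraries have fewer degrees of freedom. DESeq2 called more genes: against Ctrl 1270 for HOXA10, 1611 for HOXA11, 1761 for HOXD9, 1419 for HOXD10, 1442 for HOXD11, 1246 for HOXD12 and 1268 for HOXD13. Against the other HOX groups it called 292 for HOXA10, 280 for HOXA11, 644 for HOXD9, 224 for HOXD10, 472 for HOXD11, 451 for HOXD12 and 379 for HOXD13. It also called 13 for HOXA11 against HOXD11, 1544 for the binding groups and 7826 for any difference among HOX groups. With the series term, the counts were 2017 for HOXA11, 2285 for HOXD9, 1891 for HOXD11 and 1472 for HOXD13 against Ctrl, and 133 for HOXA10, 306 for HOXA11, 588 for HOXD9, 94 for HOXD10, 448 for HOXD11, 12 for HOXD12 and 387 for HOXD13 against the other HOX groups. They were 3 for HOXA11 against HOXD11, 3845 for HOXA13 and HOXD13 against numbers 9 to 11, 1669 for the binding groups and 202 for genes shared by the 9 comparisons with Ctrl. Within series 30 they were 2844 for HOXA11, 3378 for HOXD9, 1310 for HOXD10, 3082 for HOXD11, 2393 for HOXD13 and 4219 for all HOX groups against Ctrl, and 432 for HOXA11, 1021 for HOXD9, 123 for HOXD10, 519 for HOXD11 and 516 for HOXD13 against the other HOX groups. Series 30 also gave 5 for HOXA11 against HOXD11, 2237 for HOXA13 against HOXD13 and 2502 for any difference among HOX groups. Without HOXA9 the counts fell to 99 for HOXD11, 51 for HOXD12 and 64 for HOXD13 against the other HOX groups, 447 for the binding groups and 1549 for any difference among HOX groups. Without both series 38 libraries they were 243 for HOXD12 against Ctrl, 247 for HOXA11, 511 for HOXD9, 302 for HOXD11, 27 for HOXD12 and 245 for HOXD13 against the other HOX groups, and 84 for genes shared by the 9 comparisons with Ctrl. Fitted with only the 2 groups, edgeR called 1869 for HOXA9, 1 for HOXA10, 24 for HOXA11, 26 for HOXA13, 8 for HOXD9, 2 for HOXD10, 0 for HOXD11, 3 for HOXD12 and 0 for HOXD13 against Ctrl, 106 for HOXA13 against HOXD13 and 0 for HOXA11 against HOXD11, where the counts of 0 had 2133 (HOXD11), 2502 (HOXD13) and 795 (HOXA11 against HOXD11) genes at an unadjusted p under 0.05. The replicate numbers did not meet the rule for pairing, a correlation over 0.1 in every pair of groups: over 45 pairs, the deviations of same-numbered libraries correlated from -0.228 to 0.578 with a median of 0.127, 27 pairs over 0.1 and 10 under -0.1. They are not without structure: 6 of 512 ways of numbering gave a mean correlation as high as the real 0.134 (exact one-sided permutation p = 0.0117), libraries of 8 of 10 groups correlated better with their own number on average, and HOXA9, HOXA10, HOXD10, HOXD11 and HOXD12 correlated with each other at 0.276 to 0.578. The block moved 15 of 27 counts by over 1.5 times, all 15 up. With the replicate block, counts against Ctrl were 1118 for HOXA10, 1512 for HOXA11, 1716 for HOXD9, 1218 for HOXD10, 1376 for HOXD11 and 1150 for HOXD13. Against the other HOX groups the block gave 248 for HOXA10, 288 for HOXA11, 712 for HOXD9, 241 for HOXD10, 401 for HOXD11, 300 for HOXD12 and 310 for HOXD13, and it gave 2 for HOXA11 against HOXD11 and 1654 for the binding groups. Of the 600 list tests, 190 were called, 0 with an estimated correlation (lowest adjusted p = 0.115) and 86 by fry. With single libraries left out, 200 of 2062 recomputed list calls were lost and 14 changed direction, which touched 114 of the 190; lost were 26 of 190 with the series term, 25 of 143 within series 30, 23 of 190 without series 38, 12 of 164 without HOXA9, 8 of 190 with no filter, 5 with the block and 1 each with RLE scaling and without HOX genes. For HOXA10 against HOXD10, edgeR called 0 genes in every alternative, with 171 to 522 at an unadjusted p under 0.05, and DESeq2 called 0. Leaving out single libraries moved 112 of 306 counts by over 1.5 times, 101 of them down. The ranges against Ctrl were 2640 to 4415 for HOXA9, 153 to 774 for HOXA10, 246 to 1131 for HOXA11, 2586 to 3417 for HOXA13, 173 to 1498 for HOXD9, 221 to 870 for HOXD10, 204 to 1181 for HOXD11, 301 to 636 for HOXD12, 154 to 833 for HOXD13 and 1382 to 2930 for all HOX groups. Against the other HOX groups they were 3416 to 7273 for HOXA9, 1 to 205 for HOXA10, 20 to 236 for HOXA11, 1977 to 3549 for HOXA13, 10 to 423 for HOXD9, 3 to 128 for HOXD10, 11 to 346 for HOXD11, 17 to 427 for HOXD12 and 0 to 250 for HOXD13, where edgeR's 0 for HOXD13 had 869 genes at an unadjusted p under 0.05. They were 1289 to 2654 for HOXA9 against HOXD9, 0 to 3 for HOXA11 against HOXD11, 265 to 1039 for HOXA13 against HOXD13, 1120 to 2251 for HOXA13 and HOXD13 against numbers 9 to 11, 375 to 1297 for the binding groups, 2346 to 5197 for any difference among HOX groups, 59 to 151 for genes shared by the 9 comparisons and 180 to 229 for called list tests, with 262 to 389 unadjusted where edgeR called 0 for HOXA11 against HOXD11. The p of the same-number distance ran from 0.04167 to 0.08333 and that of the binding group distance from 0.6071 to 0.7619. Over all comparisons, 90749 of 384440 recomputed calls (23.6%) were lost with a single library left out and 113 changed sign. Lost were 13752 of 19593 (70.2%) with only the 2 groups, 5038 of 17528 (28.7%) within series 30, 7666 of 37113 (20.7%) without series 38, 3338 of 18436 (18.1%) without HOXA9, 5682 of 37117 (15.3%) with no filter, 3174 (8.55%) with the series term, 734 (1.98%) with RLE scaling, 70 (0.189%) with the block, 1307 of 36476 (3.58%) under DESeq2 and 32 of 37070 (0.0863%) without HOX genes. Sign changes numbered 89 within series 30, 48 without series 38, 28 without HOXA9, 20 with the series term and 0 in the others. The named genes were partly chosen because their calls held with each library left out, so the losses among them do not measure stability: 29 of 1978 calls there, 55 of 95 with only the 2 groups, 6 of 183 without series 38, 2 of 183 with the series term, 1 of 120 within series 30, 1 of 127 without HOXA9, and 0 under DESeq2, with RLE scaling, with no filter, with the block and without HOX genes. Depth and 2 libraries per group limit what can be called: in the simulated comparison of HOXD9 with Ctrl, 40 of 100 genes changed 2-fold were recovered.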

Other observations

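The comparisons of this part were planned, and which of their genes and lists are given here was chosen only after the values were seen; no test was added.

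In HOXA13 and HOXD13 cultures against the groups of numbers 9 to 11 (n = 4 against n = 12), further genes moved as well. The vasopressin receptor AVPR1A (4.45 ± 0.22, adjusted p = 6.86e-08, 28.5 ± 30.3 against 1.97 ± 2.84 CPM), the growth cone protein GAP43 (3.03 ± 0.21, 31.2 ± 18.5 against 3.64 ± 1.46 CPM) and the chitinase CHIA (2.93 ± 0.17) were higher. So were the guidance ligand SEMA3C (0.98 ± 0.10), the BMP antagonist GREM1 (1.12 ± 0.15) and the matrix protein TGFBI (1.13 ± 0.19), though the HOXD13 libraries lay inside the range of numbers 9 to 11 for SEMA3C (117.5 and 138.5 CPM) and GREM1 (19.9 and 19.4). AVPR1A was high in HOXA13 (40.9 and 65.5 CPM), whereas the HOXD13 libraries (3.55 and 3.96) lay below HOXD11 (6.81 and 7.76). The embryonic globin HBE (-2.82 ± 0.32), which can share reads with other globin genes, the desmosome gene PKP2 (-2.30 ± 0.21) and the steroid enzyme HSD3B2 (-2.55 ± 0.21) were lower. BMP and GDF signalling genes were higher as a list in HOXD13 against the other HOX groups (adjusted p = 4.26e-05, or 0.28 estimated). Of its members 3 of 27 rose and 1 fell, or 8 and 1 adjusted over the list alone. In the same comparison for HOXD12, 4 of 27 rose, 0 fell and 23 did not pass, against 9 higher and 0 lower adjusted over the list alone (higher, adjusted p = 0.00102, or 0.403 with an estimated correlation, and 0.0586 without HOXD12 replicate 1). Of proliferation genes in HOXD12 against the other HOX groups, 0 of 41 rose, 1 fell and 40 did not pass, against 0 higher and 2 lower adjusted over the list alone (lower, adjusted p = 4.41e-07, or 0.403 with an estimated correlation). That comparison had 174 called genes, 12 with the series term and 27 without the series 38 libraries.

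HOXA9 cultures differed from the other HOX groups in Eph receptors and ephrins, which guide cell sorting. Of 14, 1 rose and 7 fell, as over the list alone (lower, adjusted p = 0.00548, or 0.226 estimated). The ligand EFNB1 (-1.38 ± 0.11) and the receptor EPHB1 (-1.24 ± 0.12) were among those that fell. Against HOXD9, HOXA9 cultures had higher TLR3 (2.95 ± 0.58), a receptor for viral RNA, and lower BF1 (-1.59 ± 0.27). In all HOX groups against Ctrl, 10 of 45 cell adhesion and axon guidance genes rose and 5 fell (camera adjusted p = 0.402). Over the list alone, 10 rose and 9 fell. The protocadherin PCDH10 (1.65 ± 0.25) was among the rises. Of 12 fat markers in HOXA11 against the other HOX groups, 1 rose and 0 fell, as over the list alone. The list was higher (adjusted p = 0.013, or 0.237 estimated). Of WNT signalling genes in HOXD9 against the other HOX groups, 1 of 28 rose, 1 fell and 26 did not pass, against 5 higher and 10 lower adjusted over the list alone (lower, adjusted p = 0.0171, or 0.226 with an estimated correlation, and 0.101 without HOXD9 replicate 1).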
